A study of Mus musculus with 16 samples.

How the data were processed

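Whole liver RNA of C57BL/6J mice aged 12 weeks was sequenced in 16 libraries, 4 from each of 4 groups named by the labels: room air, sustained hypoxia, intermittent hypoxia, and overlap hypoxia, in which both kinds of exposure were combined per the series title. The oxygen levels, the length of the exposures and the time of day of tissue collection are not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and 1 ug of total RNA was made into libraries with an Illumina TruSeq RNA kit. The same protocol text names retina as the tissue taken, while the tissue label is liver, so the tissue was checked from marker genes.

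The deposited table holds expected counts per gene for 55487 genes, in which reads that map to several genes are shared out by estimation; 49.2% of its nonzero values are not whole numbers. Per the submitters' processing notes, Bowtie 1.3.0, RSEM and the GRCm38 genome were used; how the steps were ordered, the annotation release, the read length and the strand setting are not given in the sources used here. Because strand is not given, a gene and its antisense partner cannot be told apart in these counts. Gene symbols, coordinates and lengths were taken from the GENCODE M21 annotation of the same genome build by Ensembl gene identifier, which gave a symbol to 55227 genes. The 260 identifiers without one held at most 0.0313% of a library's counts.

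The expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14553 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with 1 coefficient per group was fitted to all 16 libraries with robust dispersion estimates, so that all comparisons share an estimate of the spread. The 7 comparisons were each exposure against room air, overlap against sustained and against intermittent hypoxia, sustained against intermittent hypoxia, and the departure of overlap hypoxia from additivity. The last is the log2 change in overlap hypoxia minus the sum of the log2 changes in both single exposures. Oxygen levels are not given, so each part need not have the same strength in the combination as alone. The departure therefore only describes how far overlap hypoxia lay from additivity on the log2 scale. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values from this fit; levels are CPM, the unit of edgeR's cpm function, with TMM scaling, given as mean ± SD over the 4 libraries of a group.

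Gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Of 45 lists, 32 of pathways and 13 of cell type markers, 43 had at least 5 members tested. Each list was tested against all other genes with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was run again with the correlation estimated from the data, and fry, which asks whether the genes of a list move in a common direction on balance without comparing them with other genes, was run as another alternative. Within each list, the members passing edgeR's test were counted after adjustment over all genes and again adjusted over the list alone. The named genes were, for each comparison against room air and for overlap against either single exposure, up to 10 with the largest rise and 10 with the largest fall among called genes with a mean of at least 2 CPM and no overlap between the values of the compared groups, passing over symbols of predicted genes. For sustained against intermittent hypoxia 5 and 5 were taken, and for the departure the 10 with the lowest adjusted p. Up to 4 members with the lowest p were taken from each described list, and 12 genes chosen in advance were taken in every comparison against room air. Some genes that met these rules are not reported here. For each named gene, the share of its 50-base words that also occur in transcripts of another gene was computed to mark genes whose counts depend on how reads were shared out.

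For a gene at 0 counts in every library of a group, the fold change was bounded with a floor of 3 counts over the group. Shares of a single library's counts have 95% Wilson intervals that reach at most 0.0172 percentage points to either side. Reads carry no molecular identifiers, so intervals and floors cover counting error only. The sample descriptions give each library a number of its own, read here as that of its animal although the labels do not call it so, and p-values measure the spread between these libraries. No libraries were duplicates: over 24 pairs within groups, chi-square per degree of freedom lay between 58.0 and 440.4. Measures per library were compared with exact two-sided permutation tests, whose smallest possible p at 4 against 4 libraries is 0.0286, and 36 such tests were adjusted together.

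Alternatives were other scalings, filters, tools (DESeq2 1.42.0 and limma-voom with quality weights), a fit of only the compared groups, the replicate number as a block, and each library left out. Added after seeing the data were offsets for gene length and GC content, the ribosomal RNA share as a covariate, removal of ribosomal and mitochondrial genes, and removal of a pair of libraries. The fit was tested on simulated counts drawn for the 14553 genes with 200 changed per comparison, and 13920 genes passed the filter. Recovery was counted over changed genes that passed. For sustained, intermittent and overlap hypoxia against room air the fit recovered 47.5%, 53.7% and 54.3% of the genes changed 2-fold. Of those changed 4-fold it recovered 86.3%, 82.7% and 77.8%, with 5, 7 and 3 false calls. All simulated groups shared a dispersion per gene, so a larger spread in some groups was not covered.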

Results

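Gene expression was measured by RNA sequencing in the livers of C57BL/6J mice kept in room air or exposed to sustained, intermittent or overlap hypoxia, with 4 libraries per group. Intermittent hypoxia is the oxygen pattern used to model sleep apnoea, sustained hypoxia that of chronic lung disease, and overlap hypoxia combines both. Library totals ranged from 10940275 counts in overlap hypoxia replicate 3 to 64789635 in sustained hypoxia replicate 2, and group means did not differ in any exact permutation test against room air (two-sided p between 0.257 and 0.943, n = 4 per group).

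The libraries matched the tissue label. Alb and Ttr, made by hepatocytes, stood at 36110 to 60620 CPM and 4992 to 9053 CPM, while of the photoreceptor genes Rcvrn was at 0 counts and Gnat1 at 2.79 to 10.6 CPM. The Y-linked genes Ddx3y (13.1 to 31.1 CPM) and Eif2s3y (21.9 to 28.4 CPM) were present in every library and Xist stayed at or below 0.0837 CPM. The adipocyte hormone gene Adipoq reached 4.10 CPM.

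The groups differed in what the libraries held. Ribosomal RNA took 25.2% ± 6.995 of the counts in intermittent hypoxia (mean ± SD, n = 4), against 5.22% ± 3.71 in room air, 2.16% ± 0.698 in sustained hypoxia and 9.59% ± 5.82 in overlap hypoxia. In each library this share equalled that of 1 annotated ribosomal RNA gene, so it measures that gene. Mitochondrially encoded genes took 8.44% ± 2.31, 2.11% ± 0.680, 1.58% ± 0.121 and 4.37% ± 2.17 in the same order. Major urinary protein genes, abundant products of male mouse liver, took 5.96% ± 3.23 in intermittent hypoxia against 20.1% ± 4.45 in room air. For each of these 3 shares the 4 intermittent hypoxia libraries lay apart from the 4 room air libraries, with an exact two-sided permutation p = 0.0286, the smallest this design allows, and 0.0791 after adjustment over 36 tests. In overlap hypoxia against room air the exact p was 0.286 for ribosomal RNA and 0.0571 for mitochondrial genes (adjusted 0.367 and 0.121). Longer genes also had higher fold changes in intermittent and overlap hypoxia, with Spearman correlations across genes between length and log2 fold change against room air of 0.299 and 0.239, and −0.138 in sustained hypoxia; genes are not independent replicates.

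**Figure D1:**
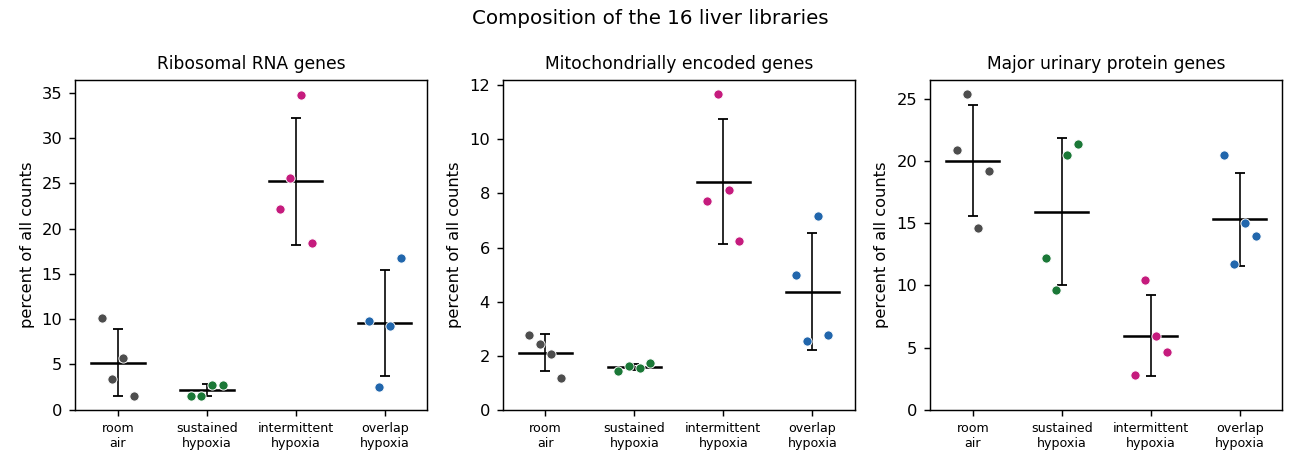
Percent of all counts (y axes) from ribosomal RNA, mitochondrially encoded genes and major urinary protein genes in the 4 groups (x axes); points are libraries, bars group means and error bars SD (n = 4). Intermittent hypoxia libraries lie at 18.5% or more for ribosomal RNA and the other libraries at 16.8% or less.

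Of 14553 genes tested, edgeR called 7 in sustained, 5404 in intermittent and 916 in overlap hypoxia against room air. The first 4 principal components of the libraries held 32.9%, 12.4%, 10.5% and 7.6% of the variance. The biological coefficient of variation was 0.229 in room air, 0.233 in sustained, 0.355 in intermittent and 0.304 in overlap hypoxia. With upper-quartile scaling in place of TMM, the median log2 fold change of all genes moved to 0.121 in intermittent hypoxia against room air and to −0.117 in sustained against intermittent hypoxia, from 0.033 and −0.034.

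**Figure D2:**
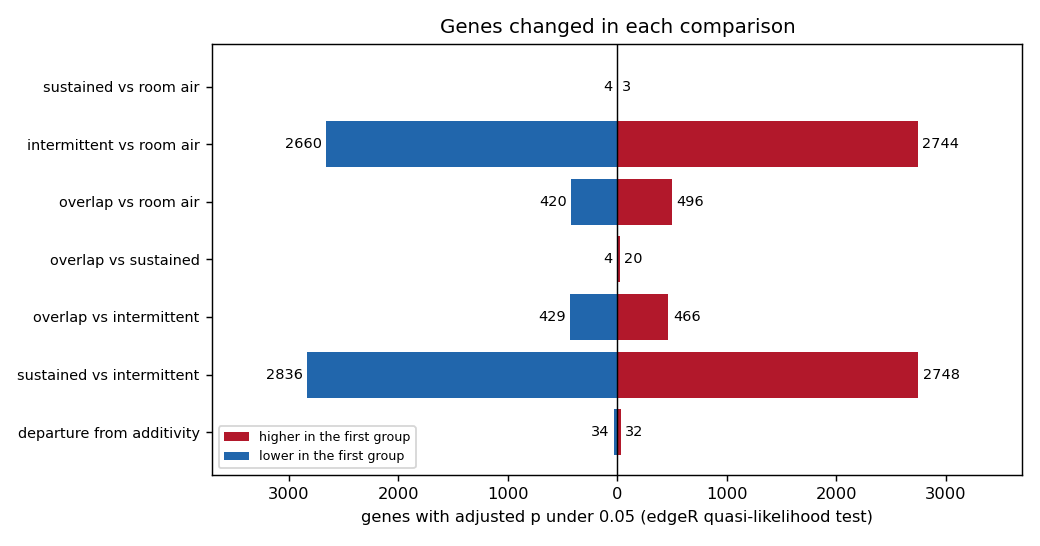
Number of genes (x axis) called higher or lower by edgeR at an adjusted p under 0.05 in each of the 7 comparisons (y axis). Bars are counts of genes. The comparisons of intermittent hypoxia with room air (2744 higher, 2660 lower) and of sustained with intermittent hypoxia (2748 higher, 2836 lower) hold the most calls.

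Among 7 genes called in sustained hypoxia against room air, a gene of glucose output and a gene of lipid storage were lower. A clock output gene was higher. Food intake and collection time are not given in the sources used here, so these differences cannot be assigned to the exposure alone. The call of Plin2, the lipid storage gene, was lost in some fits that left out a library. G6pc (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903), the catalytic subunit of glucose-6-phosphatase, which performs the last step of glucose production, fell from 144.3 ± 17.5 to 37.4 ± 14.4 CPM (log2 fold change −1.95, SE 0.25, edgeR adjusted p = 0.00525). Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), a coat protein of lipid droplets, fell from 440.3 ± 94.8 to 212.3 ± 9.16 CPM (log2 −1.05, SE 0.17, edgeR adjusted p = 0.0277). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a transcription factor driven by the circadian clock, rose from 46.6 ± 9.13 to 104.4 ± 14.5 CPM (log2 1.16, SE 0.17, edgeR adjusted p = 0.00595). Gsta2, a glutathione transferase, and Dedd2 also rose, by log2 1.09 and 0.71, and Tmem56 and the peroxisomal protein gene Hsdl2 fell by 0.74 and 0.71 (edgeR adjusted p between 0.0337 and 0.0374). Of the 50-base words of Gsta2, 64.2% also occur in other genes, so its count is uncertain.

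Several fixed lists stood apart from other genes in sustained hypoxia by camera with its preset correlation, though few of their members passed alone. Sterol synthesis genes had a median log2 fold change of 0.61 with 24 of 25 members positive and none passing; Fdps stood at 1.28 and Mvk at 0.73. The 21 fatty acid and triglyceride synthesis genes had a median of 0.40, again with none passing, and Fasn, fatty acid synthase, stood at 1.52 (edgeR adjusted p = 0.321), Elovl6 at 1.12 and the glycolytic enzyme gene Pklr at 1.03. Both lists had a camera adjusted p = 0.581 with an estimated correlation. Among 30 genes of fatty acid oxidation and PPARA targets 1 fell, Plin2, and 5 fell when adjusted over the list alone; the median was −0.17, and the hepatokine gene Fgf21 stood at −1.98. Of 19 circadian genes 1 rose, Dbp, while adjusted over the list alone 7 rose and 3 fell, with Per2 at 1.15 and Per3 at 1.15. These lists had a camera adjusted p = 0.507 with an estimated correlation.

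Kupffer cell markers, the resident macrophages of the liver, had a median of −0.59 over 14 genes, none passing over all genes and 7 falling when adjusted over the list alone, with Vsig4 at −1.06 and Folr2 at −0.97 (camera adjusted p = 0.507 with an estimated correlation). The 5 metal response genes had a median of −0.96, none passing and 3 falling when adjusted over the list alone, and Mt2 and Mt1, the metallothioneins, stood at −1.99 and −1.33. Erythroid markers had a median of 1.68 over 7 genes, none passing and 6 rising when adjusted over the list alone, and Hba-a2 stood at 356.1 ± 189.5 against 103.5 ± 43.4 CPM. Of the words of Hba-a2, 86.9% occur in other genes, and 73.5% of Mt2 lies across from a gene on the opposite strand. The metal response and erythroid lists had a camera adjusted p = 0.507 with an estimated correlation. Of 24 NRF2 targets and antioxidant enzymes, 1 rose (Gsta2) and 3 when adjusted over the list alone; the median was 0.27 and Gstm2 stood at 1.21. Pericentral genes had a median of 0.20 over 16 genes, with none passing and 3 rising when adjusted over the list alone, and Glul, glutamine synthetase, stood at 0.63. The medians of the 14 female-biased genes, 18 immediate early genes and 14 sinusoidal endothelial markers were 0.88, −0.69 and −0.18, with none passing; adjusted over the list alone 1 immediate early gene fell. These 5 lists had a camera adjusted p = 0.581 with an estimated correlation.

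Of the genes chosen in advance none passed in sustained hypoxia. Vegfa stood at 0.14, Hamp at −0.37, Cyp7a1 at 0.39, Pck1 at −0.42, Hmgcs1 at 0.55, Cpt1a at −0.02, Arntl at −2.55, Per1 at 0.51, Saa1 at −2.33 (0.78 without room air replicate 4), Hmox1 at −0.25 and Cirbp at 0.01. The 28 HIF target genes, induced by the hypoxia-inducible factors, had a median of 0.01 with none passing, and adjusted over the list alone 3 rose and 1 fell. At an unadjusted p under 0.05 the comparison held 1672 genes, where chance gives 728. The count of 7 was 177 with DESeq2, 248 with limma-voom, 61 without the filter on low counts and 91 with only the compared groups fitted, 4 with offsets for length and GC content and 3 with the ribosomal share as covariate. Single libraries mattered too. It was 2 without room air replicate 2 or 3, sustained replicate 2 or 3 or intermittent replicate 3. It was 3 without intermittent replicate 4, 12 without sustained replicate 4, 19 without room air replicate 4 and 57 without overlap replicate 2. G6pc and Dbp kept their calls in each of these leave-one-out fits. The other 5 genes lost theirs in each of the fits with 2 calls. Without room air replicate 3 the edgeR adjusted p of Dedd2, Hsdl2 and Tmem56 was 0.207, 0.207 and 0.221. Without sustained hypoxia replicate 2 that of Gsta2 and Plin2 was 0.179 and 0.110. The split of the 7 calls into 3 higher and 4 lower was 5 and 4 with DESeq2's size factors in edgeR.

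In intermittent hypoxia, transcripts of members of many fixed lists differed from room air. As many lists were called in 8 of 35 ways of splitting these libraries, and RNA composition stays open as a cause for most calls. Rises were seen in 9 of 14 female-biased and 9 of 19 circadian genes, and falls in 12 of 23 male-biased genes, 19 of 32 nuclear genes of oxidative phosphorylation, 11 of 18 chaperones and 9 of 14 Kupffer cell markers. Each of these lists had a camera adjusted p = 0.719 with an estimated correlation. Against room air 2744 genes rose and 2660 fell, and of these 1558 rose and 620 fell at least 2-fold; with upper-quartile scaling 3125 rose and 2162 fell. Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), the vascular growth factor induced by low oxygen, rose from 22.4 ± 4.48 to 67.9 ± 8.81 CPM (log2 1.60, SE 0.17, edgeR adjusted p = 6.34e-06). Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324), a repressor of the circadian clock, rose from 2.45 ± 0.510 to 18.3 ± 6.51 CPM (log2 2.90, SE 0.25, edgeR adjusted p = 1.23e-06). These libraries are also those with a ribosomal RNA share of 25.2% and a mitochondrial share of 8.44%.

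The largest rises included Cyp2b9 and Cyp2a4, cytochrome P450 genes typical of female liver, at log2 8.55 (SE 1.59) and 6.39 (SE 1.35; edgeR adjusted p = 0.00124 and 0.00277). Single libraries carried much of both rises. Cyp2b9 stood at 63.5 CPM in intermittent replicate 4 and 2.18 to 3.93 in the others, and rose by 5.91 without it; Cyp2a4 stood at 43.3 CPM in replicate 1 and 0.881 to 4.71 in the others, and rose by 3.91 without it. With limma-voom the adjusted p of Cyp2b9 was 0.0779. Fam193b rose from 4.56 ± 1.37 to 43.7 ± 10.8 CPM (log2 3.26, edgeR adjusted p = 1.31e-05), and the fibrillar collagen gene Col27a1 by 3.26, the chromatin remodeller gene Srcap by 4.06, Cyp2a22 by 3.47, the mitochondrial gene mt-Nd4l by 3.83 and Zc3h11a by 3.75. H3f3c, a histone H3.3 gene, was at 0 counts in room air and 1319 in intermittent hypoxia, at least 558.6-fold higher against a floor of 3 counts over the group. The largest falls were in Ugt2b38 and Ugt2b37, glucuronosyltransferases (−4.02 and −2.68), the major urinary protein genes Mup9 and Mup18 (−3.83 and −3.27), Zfp969 (−3.56), Selenbp2 (−3.51), Serpina12, a serpin (−3.38), the fatty acid binding protein gene Fabp5 (−3.12), Hsd3b5, a male-biased steroid dehydrogenase (−2.64), and the ribosomal protein gene Rpl10 (−2.35). Without intermittent replicate 4 Cyp2a22 rose by 2.07, and without replicate 2 Hsd3b5 fell by 3.76. For these falls the edgeR adjusted p lay between 0.00102 for Zfp969 and 0.0230 for Hsd3b5. Most words of Zfp969 (100%), mt-Nd4l (98.8%), Zc3h11a (98.7%), Mup9 (92.6%), Srcap (90.4%), Mup18 (89.6%), H3f3c (73.8%), Rpl10 (57.2%) and Selenbp2 (52.0%) also occur in other genes, so their counts depend on how reads were shared out.

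Of 23 male-biased liver genes 12 fell, none rose and 11 did not pass (median −1.31; 13 fell adjusted over the list alone). Slco1a1 (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962), an organic anion transporter, fell from 301.2 ± 27.3 to 87.9 ± 42.1 CPM, and Nudt7, a coenzyme A hydrolase of peroxisomes, from 981.4 ± 112.8 to 227.0 ± 43.6 CPM (log2 −1.78 and −2.11; edgeR adjusted p = 0.000142 and 1.35e-05). C8b and Ugt2b1 fell by 1.29 and 1.12. Of 14 female-biased genes 9 rose and 5 did not pass (median 2.29; 9 rose adjusted over the list alone). Cux2 (ENSMUSG00000042589, chromosome 5, 121856366 to 122050102), a transcription factor of female liver, had 259 counts against 2 in room air, a ratio of 164.5 with a 95% counting interval of 45.1 to 1366, and the prolactin receptor gene Prlr rose by log2 1.48. Both lists had a camera adjusted p = 0.719 with an estimated correlation, as did every other list described for this comparison. Beside these lists, major urinary protein genes took 5.96% of the counts against 20.1% in room air.

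**Figure D3:**
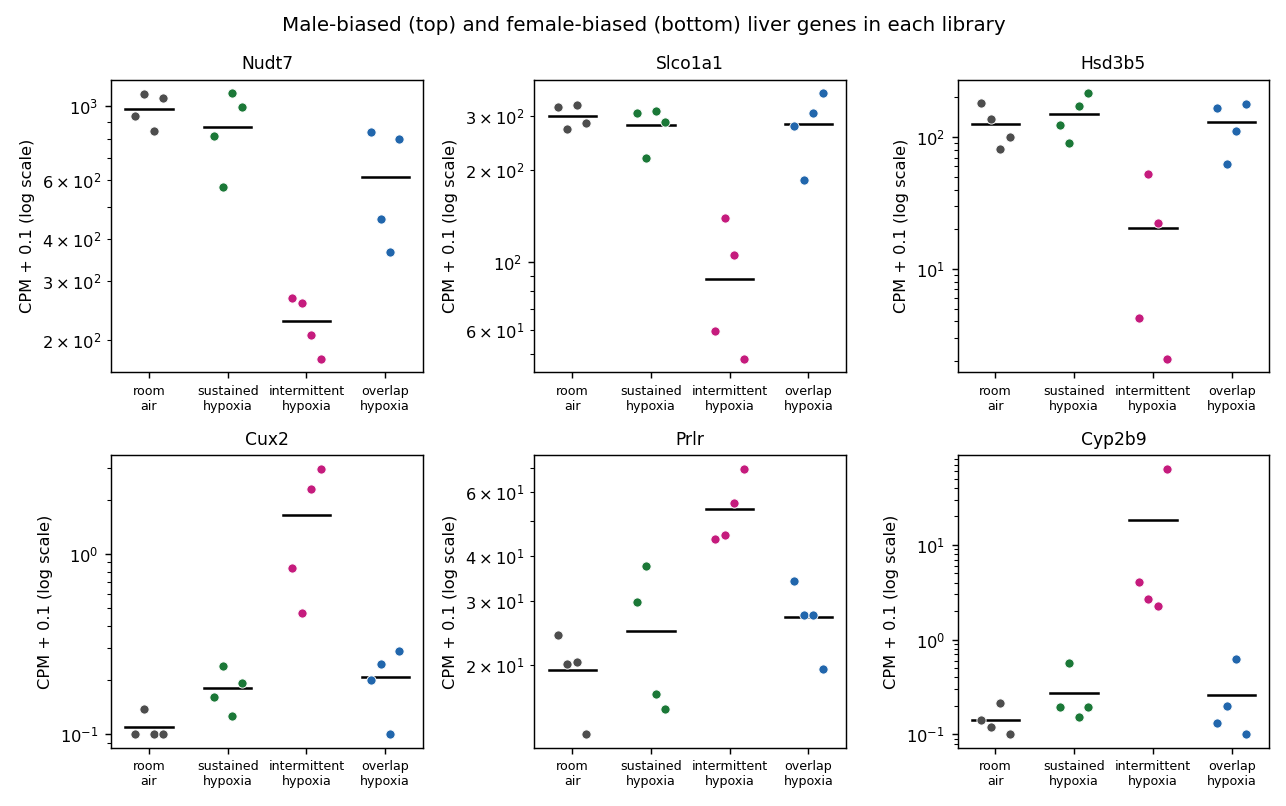
CPM plus 0.1 on a log axis (y axes) of male-biased Nudt7, Slco1a1 and Hsd3b5 and female-biased Cux2, Prlr and Cyp2b9 in the 4 groups (x axes); points are libraries and bars arithmetic group means. Slco1a1 averages 87.9 CPM in intermittent hypoxia and 301.2 in room air, and Cyp2b9 18.1 and 0.0435.

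Of 32 nuclear genes of oxidative phosphorylation 19 fell and 13 did not pass (median −0.49; 22 fell adjusted over the list alone), among them Uqcrc2 (−0.97), Cyc1 (−0.91), Ndufv1 (−0.94) and Ndufb8 (−1.10). The 13 mitochondrially encoded genes went the other way: 11 rose and 2 did not pass (median 2.26; 12 rose adjusted over the list alone), with mt-Co1 at 40020 ± 15690 against 7173 ± 2556 CPM (log2 2.48; 51.1% of the words of mt-Co1 occur in other genes) and mt-Cytb at 2.06. Ribosomal protein genes fell in 19 of 28 cases, 1 rose and 8 did not pass (median −0.53; 19 and 1 adjusted over the list alone), with Rps3 at −1.35 and Rplp0 at −1.03. Of 18 chaperones of the endoplasmic reticulum 11 fell, 1 rose and 6 did not pass (median −0.59; adjusted over the list alone 14 fell and 2 rose), including Hspa5 (−1.14), the main chaperone of that compartment, Pdia3 (−0.94), Pdia6 (−0.94) and Sdf2l1 (−1.45). Of 20 autophagy and lysosome genes 12 fell, 2 rose and 6 did not pass, also when adjusted over the list alone (median −0.53), with the mitophagy receptor gene Bnip3l at −0.91, Lamp2 at −0.83, Gabarapl1 at −0.74 and Atg5 at −0.73. For these 5 lists the camera adjusted p was 0.719 with an estimated correlation. Beside them, the libraries' mitochondrial share was 8.44% against 2.11%, and their ribosomal RNA share 25.2% against 5.22%.

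Of 30 genes of fatty acid oxidation and PPARA targets 14 fell, 1 rose and 15 did not pass, also adjusted over the list alone (median −0.47). Plin2 fell from 440.3 ± 94.8 to 155.6 ± 30.8 CPM, with the carnitine carrier gene Slc25a20 at −0.83 and Hadhb at −0.82; Cpt1a, the entry step of mitochondrial fatty acid oxidation, was the member that rose (0.66, edgeR adjusted p = 0.00181). Of 19 circadian genes 9 rose and 10 did not pass (median 0.91; 10 rose adjusted over the list alone), with Tef at 1.39, Per3 at 2.12, Per1 at 1.63 and Dbp at 0.99. Angiogenesis genes rose in 6 of 15 cases and 9 did not pass (median 0.71; 6 adjusted over the list alone), with the endothelial genes Eng (0.74), Nos3 (1.32) and Tie1 (1.13) beside Vegfa. Kupffer cell markers fell in 9 of 14 cases and 5 did not pass (median −1.03; 9 adjusted over the list alone), with Folr2 at −2.30, Adgre1 at −2.00, Clec4f at −1.45 and Cd5l at −1.33; with the ribosomal share as covariate 1 of them fell (median −0.91). These 4 lists had a camera adjusted p = 0.719 with an estimated correlation. The HIF target list did not stand apart (camera adjusted p = 0.672 with the preset correlation): 3 of 28 genes rose, 6 fell and 19 did not pass, adjusted over the list alone too, and the glycolytic genes Pgk1 (−1.21) and Gapdh (0.94) went opposite ways. For Pgk1 and Gapdh the share of words that occur in other genes was not computed. The 0.672 and the 0.719 of the other lists come from unlike settings and cannot be compared.

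**Figure D4:**
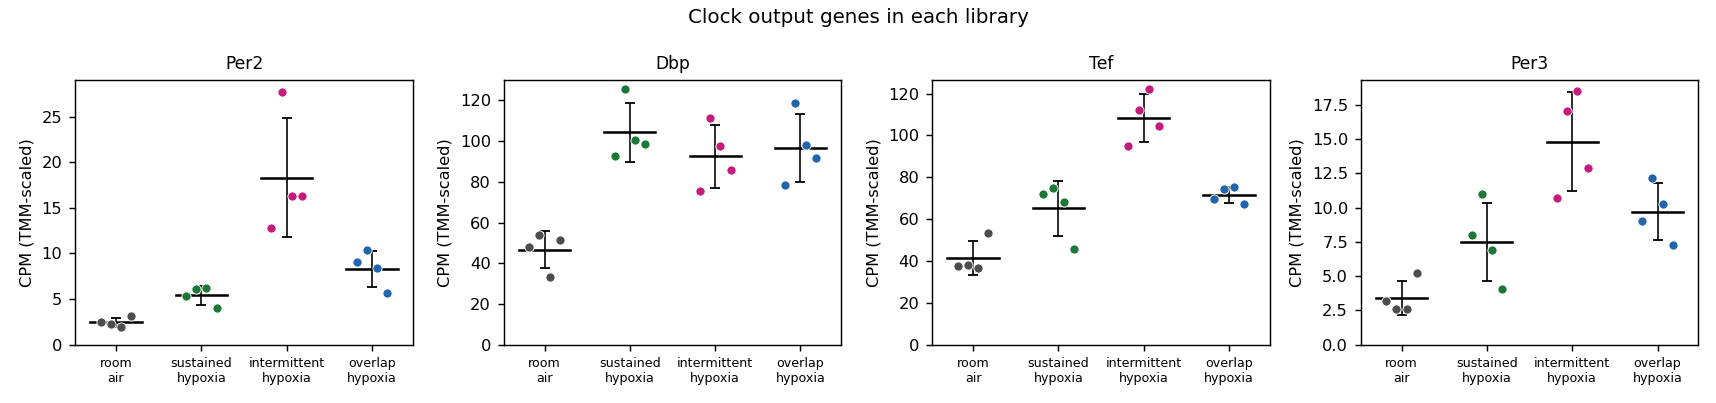
CPM (y axes) of the clock genes Per2, Dbp, Tef and Per3 in the 4 groups (x axes); points are libraries, bars means and error bars SD (n = 4). Per2 averages 2.45 CPM in room air, 5.41 in sustained, 18.3 in intermittent and 8.35 in overlap hypoxia.

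Of the other genes chosen in advance, the acute phase gene Saa1 fell by 4.25 (edgeR adjusted p = 0.0234), a call lost without room air replicate 4 (edgeR adjusted p = 0.285), whose 2502 CPM lay far above the other room air libraries. Hamp (0.16), Cyp7a1 (−0.28), Pck1 (0.26), Hmgcs1 (0.76), Fasn (0.94), Arntl (−1.09), Hmox1 (−0.36) and Cirbp (−0.19) did not pass. Calls of H3f3c and Zc3h11a were lost without room air replicate 3 (edgeR adjusted p = 0.0649) and replicate 4 (edgeR adjusted p = 0.0798). With the ribosomal share as covariate the count of called genes was 1337 in place of 5404.

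Overlap hypoxia had 9 of 14 Kupffer cell markers lower and 6 of 19 circadian genes and Vegfa higher than room air, with 496 genes that rose and 420 that fell. Both lists had a camera adjusted p = 0.289 with an estimated correlation. Adgre1 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527), which encodes the macrophage surface protein F4/80, fell from 3.44 ± 1.01 to 0.558 ± 0.149 CPM (log2 −2.55, SE 0.36, edgeR adjusted p = 0.00108). Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), a lectin of Kupffer cells, fell from 45.4 ± 14.6 to 14.1 ± 3.18 CPM (log2 −1.68, SE 0.29, edgeR adjusted p = 0.00659). Vegfa rose from 22.4 ± 4.48 to 41.3 ± 9.05 CPM (log2 0.88, edgeR adjusted p = 0.00761).

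Other large falls were in Folr2, a folate receptor of macrophages (−1.98), the lysozyme gene Lyz2 (−1.95), Wfdc17 (−1.94), the myeloid adaptor gene Tyrobp (−1.75), the complement genes C1qa and C1qb (−1.58 and −1.73), Cd55, which restrains complement (−1.58), and Insc (−1.70). For these 8 genes the edgeR adjusted p lay between 0.00118 for Folr2 and 0.0499 for Insc. Ppp1ccb was at 0 counts in overlap hypoxia and 474 in room air, with room air replicate 4 at 7.755 CPM and the other room air libraries between 0.197 and 2.01 CPM for Ppp1ccb, and 97.5% of its words occur in other genes. Rises were led by the collagen gene Col27a1 (2.57), Fam193b (2.13), the kinesin gene Kifc2 (2.12), Bcl9l, a cofactor of beta-catenin (2.11), Mbd6 (2.07), the collagen gene Col5a3 (2.05), mt-Nd3 (1.95), Sema4g (1.94), the channel gene Hcn3 (1.92) and Clasrp (1.80), with edgeR adjusted p between 0.00213 for Hcn3 and 0.0465 for Col5a3. Of the words of mt-Nd3, 98.0% occur in other genes, and 63.1% of Folr2 lies across from a gene on the opposite strand.

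Of 14 Kupffer cell markers 9 fell and 5 did not pass (median −1.36; 12 fell adjusted over the list alone), with Cd5l at −1.45 and Vsig4 at −1.27 beside Adgre1 and Folr2. The list had a camera adjusted p = 0.289 with an estimated correlation. Of 14 sinusoidal endothelial markers 4 fell and 10 did not pass (median −0.40; 6 fell adjusted over the list alone), namely Clec4g (−1.36), Kdr (−0.85), Oit3 (−0.86) and Fcgr2b (−0.82); the camera adjusted p was 0.610 with an estimated correlation. Of 9 B cell markers 1 fell, Igkc (−1.48), also adjusted over the list alone, and of 11 T and NK cell markers none passed; both medians were −1.08, and both lists had a camera adjusted p = 0.497 with an estimated correlation.

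**Figure D5:**
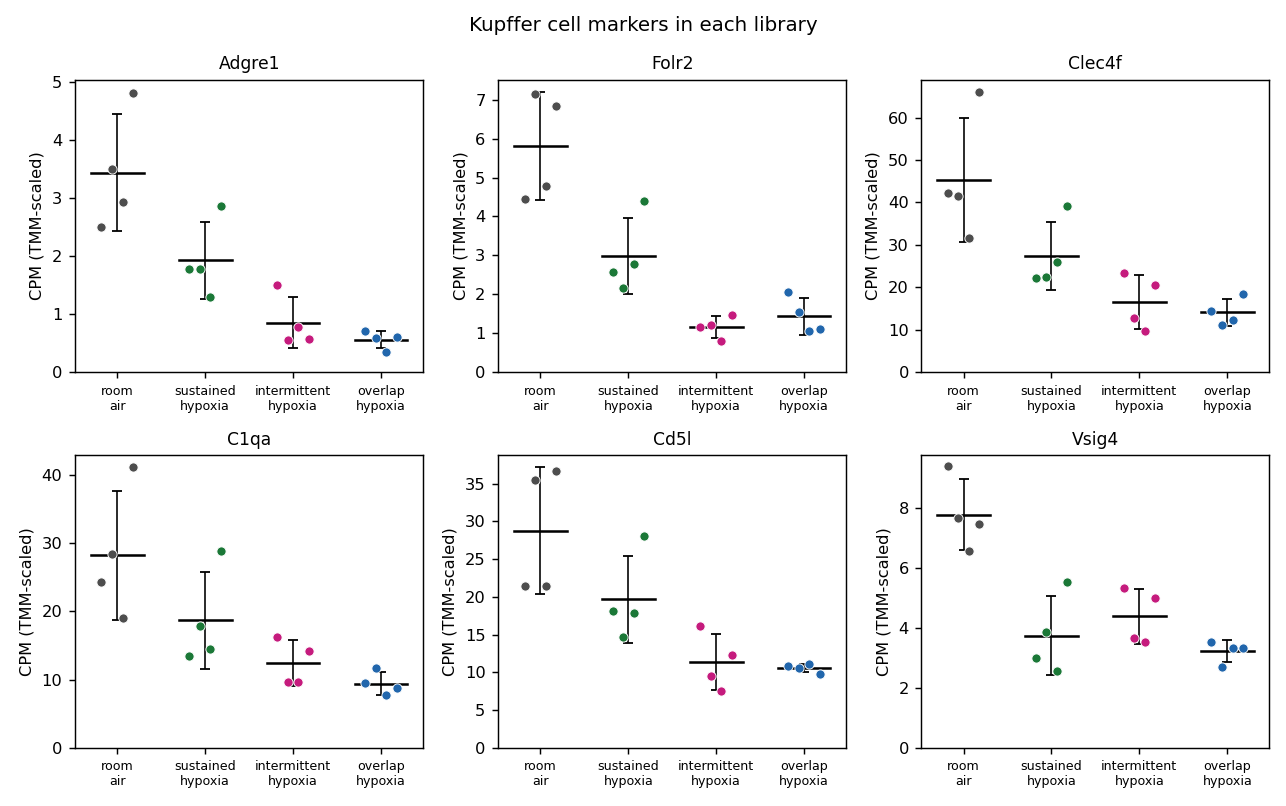
CPM (y axes) of the Kupffer cell genes Adgre1, Folr2, Clec4f, C1qa, Cd5l and Vsig4 in the 4 groups (x axes); points are libraries, bars means and error bars SD (n = 4). Adgre1 averages 3.44 CPM in room air, 1.93 in sustained, 0.854 in intermittent and 0.558 in overlap hypoxia.

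Circadian genes rose in 6 of 19 cases and 13 did not pass (median 0.58; 8 rose adjusted over the list alone), among them Per2 (1.77), Per3 (1.51), Dbp (1.05) and Tef (0.79), with a camera adjusted p = 0.289 with an estimated correlation. Of 30 genes of fatty acid oxidation and PPARA targets 4 fell, 1 rose and 25 did not pass (median −0.32; 13 and 1 adjusted over the list alone), with Plin2 at −1.28, Slc25a20 at −0.64, Acadm at −0.48 and Cpt1a at 0.52; the camera adjusted p was 0.497 with an estimated correlation. Among 22 acute phase genes 1 fell, haptoglobin (Hp, −0.84), and 6 adjusted over the list alone (median −0.47), while Hpx, which binds free haem, stood at −0.76. Of 21 urea cycle and amino acid breakdown genes Aass (−0.68) and Tdo2 (−0.62), enzymes of lysine and tryptophan breakdown, fell and Fah (0.50) rose, with 4 and 1 adjusted over the list alone (median −0.26). For both the camera adjusted p was 0.610 with an estimated correlation.

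Ribosomal protein genes fell in 3 of 28 cases (Rps3 −0.87, Rps24 −0.72, Rps14 −0.73; median −0.30; 10 adjusted over the list alone) and chaperones of the endoplasmic reticulum in 2 of 18 (Pdia3 −0.61, Pdia6 −0.52; median −0.30; 2 adjusted over the list alone), with a camera adjusted p = 0.617 and 0.699 with an estimated correlation. Of 32 oxidative phosphorylation genes 1 fell, Ndufb8 (−0.63), and 8 adjusted over the list alone (median −0.20). Of 13 mitochondrially encoded genes 2 rose, mt-Co1 (1.43) and mt-Nd3, and 3 adjusted over the list alone (median 1.03). Both had a camera adjusted p = 0.610 with an estimated correlation. Of 20 autophagy and lysosome genes Hexa (−0.70) and Ctsb (−0.49) fell and Wipi1 (0.78) rose, with 6 and 1 adjusted over the list alone (median −0.25; camera adjusted p = 0.497 with an estimated correlation). Beside these groups the mean ribosomal RNA share was 9.59% against 5.22% in room air, and the mitochondrial share 4.37% against 2.11%. The HIF target list did not stand apart (camera adjusted p = 0.649 with the preset correlation): 2 of 28 rose and 2 fell, also adjusted over the list alone.

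Hamp (−0.16), Cyp7a1 (−0.14), Pck1 (−0.14), Hmgcs1 (0.30), Fasn (1.60), Arntl (−1.72), Per1 (0.66), Saa1 (−3.84), Hmox1 (−0.61) and Cirbp (−0.16) did not pass in overlap hypoxia. Without overlap replicate 2 Hmgcs1 was at −0.31 and Fasn at 0.61, and without room air replicate 4 Saa1 was at −0.72. The rise of mt-Nd3 was 1.16, and not called, without overlap replicate 3. The 916 calls were 1492 with DESeq2, 609 with offsets for length and GC content, 362 with the ribosomal share as covariate and 272 without a pair of doubted libraries, intermittent replicate 3 with the highest ribosomal RNA share and overlap replicate 3 with the lowest total. They were 489, 174 and 273 without room air replicates 2, 3 and 4, and 278 and 229 without overlap replicates 1 and 3. Without room air replicate 3, Acadm and Fah lost their calls (edgeR adjusted p = 0.141 and 0.163), as did mt-Nd3, Tdo2 and Wipi1 (0.136, 0.118 and 0.0995). Calls lost without room air replicate 4 included Hp, Rps14, Rps24, Hexa and Ndufb8 (edgeR adjusted p between 0.0644 and 0.143). Without overlap replicate 1 those of Igkc, Col5a3, Ppp1ccb, Kdr, Oit3 and Fcgr2b were lost (edgeR adjusted p between 0.0572 and 0.148), and without overlap replicate 3 those of C1qb, Insc, Cpt1a, Aass, Ctsb, Pdia3, Pdia6 and mt-Co1 (edgeR adjusted p between 0.0770 and 0.152). With upper-quartile scaling 576 genes rose and 309 fell, in place of 496 and 420.

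Fold changes against room air were compared between exposures. Intermittent and overlap hypoxia shared 474 higher and 374 lower genes, where independent lists would share 93.5 and 76.8, and no gene was called in opposite directions. Their fold changes correlated across genes at 0.71 against 0.472 in 20 simulations of unchanged groups that shared a set of simulated controls, with a covariance of 0.426, which is 0.326 above that of the simulations. With the room air libraries split so that each comparison had its own, the mean correlation over 6 splits was 0.509 and 14 to 665 genes were shared. Sustained and overlap hypoxia shared 2 higher and 2 lower genes (independent lists 0.102 and 0.115), with a correlation of 0.433 against 0.489 simulated, a covariance of 0.138 against 0.101, and a mean correlation of 0.177 with split controls. Sustained and intermittent hypoxia shared 2 and 2 (independent lists 0.566 and 0.731), with a correlation of 0.172 against 0.490 simulated, a covariance of 0.0852 against 0.101, and 0.057 with split controls. In the simulations 0 genes were shared. Their groups were unchanged, so few calls were possible and this is no yardstick for the shared calls.

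Oxygen levels are not given, so the sustained part of overlap hypoxia need not have had the strength of sustained hypoxia alone. Comparing these groups therefore does not isolate what the intermittent component added. Overlap hypoxia differed from sustained hypoxia in 24 genes, of which 20 rose and 4 fell. G6pc was among those that rose, from 37.4 ± 14.4 to 92.2 ± 33.4 CPM (SE of the log2 fold change 0.24, edgeR adjusted p = 0.0466). The others named were Spen (2.10), a transcriptional repressor, Fam193b (1.79), the histone methyltransferase gene Kmt2a (1.61), Wdfy1 (1.47), the cyclin gene Ccnl1 (1.41), Nfat5 (1.41), a transcription factor of the osmotic response, Mapk8ip3 (1.27), the p53 inhibitor gene Mdm4 (1.27) and Als2cl (1.26). Falls were in the ribosomal protein gene Rpl9 (−1.11), the retinol dehydrogenase gene Rdh7 (−0.77), Drg1 (−0.63) and the transcription factor gene Usf1 (−0.61). The edgeR adjusted p of these 14 genes lay between 0.0382 and 0.0495, and all 14 lost their calls without overlap hypoxia replicate 1 (edgeR adjusted p = 0.212 to 0.218).

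Camera called 14 lists in this comparison, with no member passing over all genes in any of them. Mitochondrially encoded genes had a median of 1.34 over 13 genes (12 rose adjusted over the list alone), with mt-Co1 at 1.87, beside a mitochondrial share of 4.37% against 1.58% (exact two-sided permutation p = 0.0286, adjusted 0.0791, n = 4 per group). Oxidative phosphorylation genes had a median of −0.35 over 32 genes (16 fell adjusted over the list alone), ribosomal proteins −0.34 over 28 (13 fell and 1 rose), Kupffer cell markers −0.73 over 14 (8 fell), with Adgre1 at −1.72, urea cycle and amino acid breakdown genes −0.33 over 21 (3 fell), autophagy and lysosome genes −0.22 over 20 (3 fell) and periportal genes −0.36 over 16 (1 fell), with the urea cycle gene Ass1 at −0.75 (55.3% of its words occur in other genes). Circadian genes had a median of 0.36 over 19 (3 rose adjusted over the list alone), B cell markers −0.80 over 9 (1 fell) and erythroid markers −1.05 over 7. The camera adjusted p of these 10 lists was 0.606 with an estimated correlation. Sterol synthesis genes (−0.55), acute phase genes (−0.38) and drug metabolism genes (−0.19) had 0.694 and immediate early genes (0.77), with Egr1 at 2.74 and Jun at 1.91, had 0.622 as camera adjusted p with an estimated correlation.

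An unadjusted p under 0.05 was reached by 2978 genes in overlap against sustained hypoxia. The count of 24 was 86 with upper-quartile scaling, 923 with DESeq2, 1224 with limma-voom, 354 without the filter, 99 with a filter of 1 CPM in 4 libraries and 2 with only the compared groups fitted. With the ribosomal share as covariate edgeR called 0 (534 at an unadjusted p under 0.05) and without the pair of doubted libraries 0 (2345). Leaving out a library gave 0 calls for sustained replicates 1 and 4 and overlap replicates 1 and 3 (2429, 2643, 2009 and 2162 at an unadjusted p under 0.05), 1 for intermittent replicate 1, 2 for room air replicate 2, sustained replicate 3 and intermittent replicate 3, 3 for sustained replicate 2, 14, 15, 43, 48 and 95 for room air replicate 3, intermittent replicates 4 and 2 and room air replicates 1 and 4, and 1547 for overlap replicate 2.

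Overlap hypoxia was also compared with intermittent hypoxia, which for the same reason does not isolate what the sustained component added. It had 5 of 23 male-biased genes higher and 4 of 14 female-biased and 9 of 14 sinusoidal endothelial genes lower, and these lists had a camera adjusted p = 0.784 with an estimated correlation. Of 895 called genes 466 rose and 429 fell. These calls rest on an estimate of the spread shared by all 4 groups. The biological coefficient of variation was 0.355 in intermittent and 0.304 in overlap hypoxia, against 0.229 in room air and 0.233 in sustained hypoxia. With only the compared groups fitted edgeR called 0 genes, and whether the shared estimate explains this was not tested. Slco1a1 rose from 87.9 ± 42.1 to 282.4 ± 72.3 CPM (log2 1.68, SE 0.27, edgeR adjusted p = 0.00955) and Nudt7 from 227.0 ± 43.6 to 614.9 ± 237.1 CPM (log2 1.44, SE 0.25, edgeR adjusted p = 0.00969). Of 23 male-biased genes 5 rose and 18 did not pass (median 1.31; 13 adjusted over the list alone), including C8b (1.00), and of 14 female-biased genes 4 fell and 10 did not pass (median −1.59; 8 adjusted over the list alone), namely Cux2 (−3.61), Cyp2b9 (−7.72), Cyp2a4 (−6.26) and Prlr (−0.99). Without intermittent replicate 4 for Cyp2b9, and without replicate 1 for Cyp2a4, both fell less. The camera adjusted p of both was 0.784 with an estimated correlation. Beside them, ribosomal RNA took 9.59% of the counts against 25.2% in intermittent hypoxia, and major urinary protein genes 15.3% against 5.96% (exact two-sided permutation p = 0.0286 each, adjusted 0.0791, n = 4 per group).

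Further rises were in Selenbp2 (3.75), Fabp5 (3.21), Adgrv1 (1.75), the kinase gene Mapkapk3 (1.66), the urinary protein gene Mup20 (1.52), the transporter gene Slc22a28 (1.44), Olfml1 (1.22) and Serpina3k (1.21), and further falls in the metallothionein genes Mt2 and Mt1 (−2.57 and −1.92), Srcap (−2.25), Lrit2 (−1.92), Fbf1 (−1.65), the cytochrome P450 gene Cyp2j9 (−1.59), Nfat5 (−1.57) and the lipid phosphatase gene Plpp1 (−1.56), with edgeR adjusted p between 0.00707 for Lrit2 and 0.0487 for Srcap. Of their words, 53.9% of Slc22a28 and 50.5% of Mup20 occur in other genes. Without overlap replicate 1 Srcap was at −3.35. Sinusoidal endothelial markers fell in 9 of 14 cases and 5 did not pass (median −0.81; 11 adjusted over the list alone), with the scavenger receptor genes Stab1 (−0.85) and Stab2 (−0.95) and Fcgr2b (−1.02). Angiogenesis genes fell in 4 of 15 (median −0.68; 6 adjusted over the list alone), namely Tek (5.11 ± 0.787 to 2.54 ± 0.299 CPM), Kdr (−0.86), Vegfa (−0.72) and Eng (−0.68). Autophagy and lysosome genes rose in 4 of 20 (Wipi1 0.95, Gabarapl1 0.53, Bnip3l 0.52, Atg5 0.43; median 0.22; 5 adjusted over the list alone). For these 3 lists the camera adjusted p was 0.784 with an estimated correlation. Oxidative phosphorylation genes rose in 5 of 32 (median 0.25; 8 adjusted over the list alone), with Uqcrc2 at 0.61 and Atp5b at 0.58, and chaperones of the endoplasmic reticulum in 1 of 18, Hspa5 (0.71; median 0.31; 4 adjusted over the list alone). Mitochondrially encoded genes had a median of −1.09, none passing and 8 of 13 falling adjusted over the list alone, and ribosomal proteins a median of 0.27 with none passing in either way. These 4 lists had a camera adjusted p = 0.812 with an estimated correlation.

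Most calls of overlap against intermittent hypoxia depended on a single library: without overlap replicate 4 edgeR called 16 genes. Of the genes named, Slco1a1, Lrit2 and Cyp2j9 kept their calls in each leave-one-out fit. The others lost theirs, most without overlap replicate 4, such as Nudt7, Cux2, Cyp2b9, Stab1 and Vegfa (edgeR adjusted p = 0.0508, 0.0596, 0.0866, 0.0657 and 0.0829). Adgrv1, Atg5 and Atp5b had their highest value without intermittent replicate 2 (edgeR adjusted p = 0.124, 0.156 and 0.154). The count was 171, 217 and 1406 without intermittent replicates 2, 3 and 4 and 451 without overlap replicate 2, and 0 with only the compared groups fitted by edgeR, where 2743 genes had an unadjusted p under 0.05. DESeq2 called 1616 and limma-voom 494. It was 37 with the ribosomal share as covariate and 354 without the pair of doubted libraries. With upper-quartile scaling 312 genes rose and 457 fell.

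Sustained against intermittent hypoxia gave 5584 calls, 2748 higher and 2836 lower in sustained hypoxia, and with upper-quartile scaling 2276 higher and 3188 lower. Male-biased genes were higher in 11 of 23 cases (12 adjusted over the list alone) and oxidative phosphorylation genes in 23 of 32 (median 0.62; 24 adjusted over the list alone), while all 13 mitochondrially encoded genes were lower (median −2.48; 13 adjusted over the list alone). Ribosomal proteins were higher in 22 of 28 cases and lower in 1 (median 0.57; 23 and 1 adjusted over the list alone). Chaperones of the endoplasmic reticulum (8 of 18 higher, 1 lower), urea cycle and amino acid breakdown genes (10 of 21, 1 lower), periportal genes (8 of 16, 1 lower) and autophagy and lysosome genes (13 of 20, 1 lower) had more members higher than lower. Members that passed were all lower among circadian genes (8 of 19), angiogenesis genes (8 of 15), sinusoidal endothelial markers (6 of 14) and immediate early genes (4 of 18). Adjusted over each of these 8 lists alone the counts were 9 and 2, 10 and 1, 8 and 1, 13 and 1, 10, 9, 6 and 2. For all 12 lists the camera adjusted p was 0.730 with an estimated correlation. Named genes were Selenbp2 (3.70), Zfp969 (3.50), Ugt2b38 (3.35), Serpina12 (3.25) and Ppp1ccb (6.85) on the higher side, and Cyp2b9 (−6.48), the nuclear noncoding RNA Malat1 (−4.19), mt-Nd4l (−3.98), Srcap (−3.81) and Nr4a1 (−3.46), an immediate early nuclear receptor, on the lower. Beside these, ribosomal RNA took 2.16% of the counts against 25.2%, and with that share as covariate 14 genes were called and none of these 10. Cyp2b9 was less far below 0 without intermittent replicate 4, and Ppp1ccb had counts in intermittent replicate 2 only (0.236 CPM). The call of Nr4a1 was lost without sustained hypoxia replicate 3 (edgeR adjusted p = 0.0904).

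Overlap hypoxia departed from the sum of both single exposures in 66 genes, 32 above and 34 below it (31 and 47 with upper-quartile scaling). Per2 lay 2.28 log2 units below the sum (−2.28, SE 0.33) and Gsta2 −1.83 (SE 0.26), each with an edgeR adjusted p = 0.00714: Gsta2 stood at 18.1 ± 3.72 CPM in room air, 38.7 ± 12.5 in sustained, 64.4 ± 3.77 in intermittent and 38.7 ± 2.63 in overlap hypoxia. Tef (−1.25), the kinase gene Mknk2 (−1.51) and the anchoring protein gene Akap8 (−1.20) also lay below the sum, and Pllp (1.57, edgeR adjusted p = 0.0215), Aasdhppt (1.01), Dhx40 (0.89), the tubulin gene Tubb4b (1.07) and Unc119b (1.20) above it; apart from Pllp their edgeR adjusted p was 0.0373. Of the words of Tubb4b, 50.9% occur in other genes, and 54.1% of Pllp lies across from a gene on the opposite strand. Among the lists, 3 of 19 circadian genes departed downward (median −0.71; adjusted over the list alone 6 down and 1 up), with Dbp at −1.10, and 2 of 23 male-biased genes upward (median 1.23; 4 adjusted over the list alone), Nudt7 at 1.61 and Slco1a1 at 1.78. Of 14 female-biased genes 1 departed downward, Cux2 (−6.36), with 2 counts in room air, and 9 adjusted over the list alone (median −2.47). These 3 lists had a camera adjusted p = 0.842 with an estimated correlation. Of 30 genes of fatty acid oxidation and PPARA targets 1 departed upward, Plin2 (1.27), and 3 adjusted over the list alone (median 0.37; camera adjusted p = 0.882 with an estimated correlation). Camera also called 7 lists in which no member passed, with medians of −0.53 for sterol synthesis, 0.47 for chaperones of the endoplasmic reticulum, −0.66 for mitochondrially encoded genes, −0.48 for pericentral genes, −0.70 for angiogenesis, −0.51 for sinusoidal endothelial markers and −1.59 for erythroid markers. Adjusted over the list alone 1 angiogenesis gene departed, and these lists had a camera adjusted p = 0.845 to 0.890 with an estimated correlation.

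The count of 66 was 554 with DESeq2, 272 with limma-voom, 192 without the filter, 32 with offsets for length and GC content and 7 without the pair of doubted libraries. Leaving out a library gave 2 for room air replicate 2, sustained replicate 1, intermittent replicate 3 and overlap replicate 4, 3 for room air replicate 3 and sustained replicate 2, 4 for intermittent replicate 2, 5 for sustained replicate 3, 26 and 42 for room air replicates 4 and 1, and 133, 213 and 241 for overlap replicate 3, intermittent replicate 4 and overlap replicate 2. Without sustained replicate 2 the edgeR adjusted p of Tef, Akap8, Mknk2, Aasdhppt, Dhx40, Tubb4b, Unc119b and Plin2 was 0.101, and that of Cux2, Dbp, Nudt7 and Slco1a1 0.125, 0.129, 0.124 and 0.140. Pllp lost its call without room air replicate 2, sustained replicate 1, intermittent replicate 3 (edgeR adjusted p = 0.0830) or overlap replicate 4. Gsta2 and Per2 kept theirs in each leave-one-out fit and were the only calls in those with 2.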

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

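The tests of RNA composition, of gene length and GC content, and of other cell types were chosen after the result was seen, while those of shared reads, of a single animal, of room air replicate 4 and of other splits of the libraries were planned.

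The breadth of the change in intermittent hypoxia, 5404 genes against room air, came from libraries with a ribosomal RNA share of at least 18.5%, where the other 12 libraries had at most 16.8%. Offsets for length and GC content brought the rank correlation of fold change with length from 0.299 to 0.005 and left 70.3% of the calls in the same direction (3797 of 5404), so bias by length and GC content was not the source of most calls. Slopes of genes on the ribosomal share within sustained and overlap hypoxia correlated at −0.02 with the fold changes, but such slopes correlated at only 0.147 between room air and overlap hypoxia, too weakly for this test to decide. RNA composition therefore stays open for most calls, because the shares of this group and of the others do not overlap. With the share as covariate 1337 genes were called, 1255 of them among the 5404. The median size of the log2 change of the 5404 went from 0.87 to 0.75 and the median standard error from 0.20 to 0.30. Calls were thus lost with both a smaller change and a larger standard error.

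The fall of male-biased and rise of female-biased genes in intermittent hypoxia was tested against 3 technical explanations. With the ribosomal share as covariate, which took the genes called from 5404 to 1337, the medians were −2.22 (95% bootstrap interval over genes −3.00 to −1.81) and 3.35 (1.38 to 6.11), so both lists kept their directions. The shares of intermittent hypoxia and of the other groups do not overlap, so this fit extends slopes within groups beyond their range. The intervals cover the spread over genes, not between animals. The covariate therefore cannot decide whether RNA composition was the cause. Of 12 male-biased genes that passed 10 still did, and of 9 female-biased genes 5, as the median standard errors rose from 0.48 to 0.75 and from 0.84 to 1.22. Shared reads did not account for it, since the 10 male-biased members with at least 90% of their words in no other gene had a median of −1.54 (7 fell), and no single animal did, since the highest median without an intermittent hypoxia library was −1.16. The exposure itself stays open as an untested explanation, as does RNA composition. Food intake, collection time and processing batch, which are not given in the sources used here, stay open too.

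The fall of Kupffer cell markers in overlap hypoxia was also tested against 3 explanations. The median of the list lay 1.27 below that of 38 pooled endothelial, stellate and cholangiocyte markers (−1.27, 95% bootstrap interval over genes −1.84 to −0.61). The pooled lists were unlike, with medians of −0.40 for sinusoidal endothelial, −0.15 for stellate and fibroblast and 0.49 for cholangiocyte markers. These medians differ from an equal fall of all cells other than hepatocytes. Intervals here cover the spread over genes, not between animals, so they do not settle it. B cell and T and NK cell markers, not in the pool, had medians of −1.08 each, so a lower share of immune cells as a whole stays open. With the ribosomal share as covariate, which took the genes called from 916 to 362, the median was −1.31 (−1.63 to −0.87) with 8 genes that fell, so the trend with that share was not the whole cause, and without room air replicate 4 the median was −1.3 with 8 genes that fell. Fewer Kupffer cells or less transcript per cell may each explain it, and whole-liver RNA cannot separate them.

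For most pairs of groups, no other split of their libraries gave as many called genes as the real one. Ranking first is the most that 35 splits can show, and no adjustment was made over the comparisons. Chance in how the libraries were grouped is therefore less likely for these counts but not excluded. The libraries of the compared groups were split in each of the 35 possible ways, and for the departure 100 splits were used, the real one and others drawn at random. A count as large as the real one came in 1 of 35 splits, the real one, for sustained (7 genes, highest other 0), intermittent (5404, highest other 2) and overlap hypoxia (916, highest other 149) against room air, for overlap against intermittent hypoxia (895, highest other 41) and for sustained against intermittent hypoxia (5584, highest other 0). For the departure it came in 1 of 100 (66, highest other 55). Those random splits mixed all 4 groups, so differences between the groups entered the spread within them. That lowers the calls whether or not the exposures add up, so chance was not excluded for the departure. For overlap against sustained hypoxia chance could not be excluded: 2 of 35 splits gave as many as the real 24. The highest other gave many times that count, which points to a structure among these libraries other than their groups; what it is was not tested.

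For the counts of gene lists called by camera with its preset correlation, chance could be excluded in no comparison. As many lists came in 15 of 35 splits for sustained hypoxia against room air (12 lists, highest other 22), in 8 for intermittent (11, highest other 16), in 13 for overlap (13, highest other 18), in 16 for overlap against sustained (14, highest other 18), in 14 for overlap against intermittent hypoxia (9, highest other 16) and in 51 of 100 for the departure (11, highest other 18). With the correlation estimated from the data 0 lists were called in any comparison (camera, unadjusted p under 0.05 in 3, 2, 3, 1, 2, 1 and 1 lists), and fry called 0, 17, 6, 1, 4, 16 and 0, in the order sustained, intermittent and overlap hypoxia against room air, overlap against sustained, overlap against intermittent, sustained against intermittent hypoxia, and departure.

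Dixon's test at the level of 1 in 20 marked a single library in 12 of 108 groups, made of 21 genes and 6 library measures in 4 groups. In room air, replicate 4 had Saa1 at 2502 CPM (others 47.6 to 141.4) and Lyz2 at 96.9 (48.9 to 51.5), and replicate 2 Cux2 at 0.0377 (others 0). In sustained hypoxia, replicate 3 had G6pc at 58.7 (27.5 to 32.3), and replicate 2 Plin2 at 225.8 (206.1 to 209.1) and Cyp2b9 at 0.469 (0.0532 to 0.0932). In intermittent hypoxia, replicate 1 had Saa1 at 71.2 (19.7 to 27.6) and Cyp2a4 at 43.3 (0.881 to 4.71), and replicate 4 Cyp2b9 at 63.5 (2.18 to 3.93). In overlap hypoxia, replicate 3 had Plin2 at 125.7 (197.0 to 200.7), replicate 2 Fasn at 386.4 (69.7 to 86.4) and replicate 4 Lyz2 at 21.4 (13.8 to 14.4).

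Overlap hypoxia departed from the sum of both single exposures in 66 genes, led by Gsta2 (−1.83), Per2 (−2.28), Pllp (1.57), Tef (−1.25), Aasdhppt (1.01), Dhx40 (0.89), Akap8 (−1.20), Mknk2 (−1.51), Tubb4b (1.07) and Unc119b (1.20).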

How the results depend on the processing

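The cause of each difference given here was not tested. Numbers of genes are edgeR calls unless another tool is named, and numbers of lists are camera calls.

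With DESeq2, sustained hypoxia against room air gave 177 genes in place of 7, overlap against room air 1492 in place of 916, overlap against sustained 923 in place of 24, overlap against intermittent 1616 in place of 895 and the departure 554 in place of 66. Limma-voom gave 248 for sustained hypoxia against room air, 1224 for overlap against sustained, 494 for overlap against intermittent and 272 for the departure. Upper-quartile scaling gave 86 for overlap against sustained hypoxia.

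Without the filter, counts were 61 for sustained hypoxia against room air, 354 for overlap against sustained and 192 for the departure, with 18 lists for intermittent hypoxia in place of 11 and 17 for the departure in place of 11. A filter of 1 CPM in 4 libraries gave 99 for overlap against sustained hypoxia. Fitting only the compared groups gave 91, 2 and 0 for sustained against room air, overlap against sustained and overlap against intermittent (2743 unadjusted p under 0.05 in the last). The replicate number as a block gave 21, 126 and 290 for sustained against room air, overlap against sustained and the departure. The labels do not say that a number pairs libraries, and the data gave a weak hint only: 24 pairs of the same number had a mean correlation of deviations of 0.036 against −0.012 for 72 other pairs, 4 exceeded 0.1, and 8 of 16 libraries were closest to one of their own number. A log2 fold change of at least 1 left 4, 2178, 270, 262 and 2210 for sustained, intermittent and overlap hypoxia against room air, overlap against intermittent and sustained against intermittent, by construction.

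Chosen after seeing the data, offsets for length and GC content gave 4, 609 and 32 genes for sustained and overlap hypoxia against room air and the departure, with 6 lists for intermittent hypoxia and 5 for overlap against sustained in place of 14. The ribosomal share as covariate, also chosen after, gave 3, 1337 and 362 for sustained, intermittent and overlap hypoxia against room air, 0 for overlap against sustained (534 unadjusted), 37 for overlap against intermittent and 14 for sustained against intermittent, with 17 lists for intermittent hypoxia. Without the pair of doubted libraries, intermittent replicate 3 and overlap replicate 3, counts were 272 for overlap against room air, 0 against sustained (2345 unadjusted), 354 against intermittent and 7 for the departure.

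Leaving out each library gave 2 to 57 genes for sustained hypoxia against room air, 174 to 1186 for overlap against room air, 0 to 1547 for overlap against sustained, 16 to 1406 for overlap against intermittent and 2 to 241 for the departure. It gave 11 to 19 lists for sustained hypoxia (19 without sustained replicate 2) and 9 to 17 for the departure (17 without sustained replicate 4).

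With an estimated correlation camera called 0 lists in each comparison, and fry called 0, 17, 6, 1, 4 and 0 for sustained, intermittent and overlap hypoxia against room air, overlap against sustained, overlap against intermittent and the departure. The 399 named gene results had 11065 alternative values. Whether the gene was called stayed the same in 9732, a call was lost in 1009 and gained in 324, and 0 went in the opposite direction. Results called in neither fit count among the 9732 whatever their fold change, so this count does not measure how stable the fold changes were. Direction was counted only where the value or its alternative was called; Saa1 in sustained hypoxia against room air, called in neither, went from −2.33 to 0.78 without room air replicate 4.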

Other observations

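The test of the clock described here was chosen after the result was seen.

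The mean log2 level of 6 clock output genes lay 0.77, 1.59 and 1.06 above room air in sustained, intermittent and overlap hypoxia. This difference was not tested, and the circadian list had a camera adjusted p = 0.507, 0.719 and 0.289 with an estimated correlation, so no change of the group is claimed. A shift of the clock's phase would change genes of the opposite phase the other way. The mean of 4 genes of the opposite phase lay at −0.87, −0.46 and −0.34 relative to room air (exact two-sided permutation p = 0.0286, 0.114 and 0.143, smallest possible 0.0286, n = 4 per group; adjusted 0.0857, 0.143 and 0.143). A hypothesis is that the exposed livers may have been at another clock phase, and this test left it open; the time of collection, which would produce the same pattern, is not given in the sources used here.

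G6pc gave another unplanned observation. It stood at 144.3 CPM in room air, 37.4 in sustained, 151.5 in intermittent and 92.2 in overlap hypoxia.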
